A study of Mus musculus with 6 samples.

How the data were processed

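The series holds 6 lens samples of mice at postnatal day 30, 3 Tdrd7 heterozygous and 3 Tdrd7 null, as the labels' genotype field gives them. Per the labels' protocols, total RNA was extracted with the Qiagen RNeasy mini kit, treated with DNase and checked on an Agilent Bioanalyzer, and biotinylated cRNA was made with the Illumina TotalPrep kit for hybridisation to Illumina arrays. The scanner and summary software and their versions are not given in the sources used here. The deposited raw table holds 1 intensity per probe and array on a linear scale, with medians from 60.5 to 71.3 and no value under 37.5, so it was taken as neither background-subtracted nor normalized. Per the file headers, a detection p-value stands beside each intensity. Its steps are multiples of 1 over 936, as for ranks against 936 negative control probes, which the deposited table does not list. The raw columns name the group but not the replicate number, so the 6 arrays were assigned by group alone and are called heterozygous arrays 1 to 3 and null arrays 4 to 6. The authors' series matrix holds a further intensity per probe and sample, on a linear scale, with column medians of 65.4, 66.2 and 64.8 for heterozygous replicates 1, 2 and 3 and 65.7, 66.2 and 64.8 for null replicates 1, 2 and 3. Each of its columns is a straight-line rescaling of 1 raw column (rank correlation 1, largest residual 0.017), its scale is linear and its direction that of brightness, and the method of the rescaling is unknown. By the medians, the columns that heterozygous array 2 and null array 5 rescale to are those of replicate 2 in each group. This match by values was not used to assign the arrays. The series matrix was used only as an alternative source of values.

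Intensities were background-corrected, normalized and log2-transformed by the neqc method of limma 3.58.1 in R 4.3.3, that is normexp with negative control means and variances inferred from the detection p-values, an offset of 16 and quantile normalization. The offset pulls differences of dim probes toward 0, while background correction widens them. The median difference of the leucocyte markers, most of them dim, was 2.26 with both and 1.27 with no background correction. Of 45281 probes, the 14902 with a detection p under 0.05 on at least 3 of 6 arrays were tested with lmFit and eBayes, null against heterozygous, two-sided, with Benjamini-Hochberg adjustment over these probes and a threshold of 0.05. Gene symbols came from the platform's annotation table, in which 34885 probes have 1 gene, 18 have several and 10378 have none, and no gene was named from a probe with several. Of the probes tested, 12934 had 1 gene, giving 8944 genes, each represented in gene lists by its probe with the highest mean. Other probes are given for some of the named genes. A probe detected on 0 of 3 arrays of a group has only a bound there, computed per array against the higher of its own signal and the lowest signal among detected probes. Intensities are relative, so a difference is set against the bulk of the probes, whose median difference was 0.01.

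The probes detected were 15640, 12655 and 14203 on heterozygous arrays 1, 2 and 3 and 15028, 16204 and 14826 on null arrays 4, 5 and 6. The first principal component (42.9% of the variance) set heterozygous array 2 apart from the others, and the second (31.7%) null array 5. The fit was tested on simulated data for this comparison, with 14902 probes of which 200 were changed. Of 100 probes changed by 1 on the log2 scale 10% were recovered, of 100 changed by 2 83% were, and 8 of 101 calls were of unchanged probes. On the simulated gene lists, the 1 list that was shifted passed and 0 of the unshifted lists did. The simulated probes varied independently, so this does not test lists whose genes are correlated, as estimated at 0.93 for leucocyte markers. On the real arrays, 9 of the 10 splits into 3 and 3, the real one included, gave at least 2 lists.

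Before the data were examined, 29 gene lists were fixed from textbook knowledge of the lens, of Tdrd7 and of tissues that can adhere to a dissected lens, together with the tests, the naming rule and most alternatives. Of 750 list entries, 688 had a named probe on the array, and 27 lists had at least 5 genes among those tested. Corneal and conjunctival epithelium markers and muscle markers had 4 each and were not tested (median differences −0.20 and 0.00). Lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the 27 lists, and again with an estimated correlation and with fry. Members were also counted with the p adjusted over the list alone. The naming rule took Tdrd7, Hspb1 and Crybb3, up to 12 rises and 12 falls past the threshold without overlap between groups (filled to 6 by the smallest p), and up to 4 members per list with the smallest p, of which the clearest are given. Genes near Tdrd7 were compared with the rest by Fisher's exact test, with 50 tested genes on each side in the order of the RefSeq annotation of GRCm38.p6, which was used only for chromosome and order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

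Both groups carry replicate numbers 1 to 3 in the labels, which do not say what the numbers mark. After centring each group, same-numbered samples correlated across probes at 0.10, 0.34 and 0.53, each over 0.1 before rounding, so by the rule set beforehand the numbers were taken to pair the samples, although the first pair lies barely above that bound and 1 differently numbered pair reached 0.12. The fit with the number as a block was run only on the series matrix values, whose columns carry the numbers, after normexp with an offset of 16 and quantile normalization. All other fits, the main one and its p-values included, leave the pairing out. The other alternatives were the background correction, the offset, the normalization, the filter on dim probes, the variance model, array weights, the set test and its correlation, the thresholds, the window around Tdrd7 and leaving out each array in turn. A fit without heterozygous array 2 and null array 5, and one on the series matrix values without the block, were added after the data were seen. The slide as a block was not run, because no slide is given in the table used here.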

Results

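Total RNA from mouse lenses at postnatal day 30 was measured on 6 Illumina mouse BeadArrays, on which the brightness of each bead-bound probe reports the abundance of 1 transcript. The 6 samples formed 2 groups, 3 from Tdrd7 heterozygous and 3 from Tdrd7 null mice, all of a mixed C57BL/6J and C3A.Blia strain. Tdrd7 encodes a Tudor domain protein of cytoplasmic RNA granules, and loss of the gene is known to cause cataract. The series design sets the null lenses against the heterozygous lenses, and the comparison asks which lens transcripts differ between them. Heterozygous arrays are numbered 1 to 3 and null arrays 4 to 6, after the order of the deposited raw table. The number of probes detected ran from 12655 on heterozygous array 2 to 16204 on null array 5, of 45281 on the array. Log2 intensities of heterozygous array 2 correlated across probes at no more than 0.947 with any other array, and those of null array 5 at no more than 0.963, while the best correlation of each of the other 4 arrays was at least 0.982. Only 3 samples per group limit the precision, and an exact two-sided permutation test of 3 against 3 cannot go below p = 0.1. The labels do not say whether the samples of a group came from separate animals, so all p-values measure the spread between these samples, which may be technical.

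The Tdrd7 transcript was 15.1-fold lower in the null lenses. Its log2 intensity was 10.06 ± 0.43 (SD, n = 3) in null and 13.98 ± 0.23 (n = 3) in heterozygous samples, a difference of −3.92 ± 0.26 (SE), with an adjusted p of 0.00118 by limma with Benjamini-Hochberg adjustment. Tdrd7 was lower in 3 of 3 null samples and had the smallest p of the 14902 probes tested. The Tdrd7 signal stayed above background on all 3 null arrays. Where this probe lies relative to the mutation was not analysed here, so its fall follows the sample labels but does not show which part of the transcript is lost. Hspb1, a small heat shock protein that keeps other proteins soluble, was at 12.41 ± 0.31 in null and 13.22 ± 0.14 in heterozygous lenses. The Hspb1 difference of −0.81 ± 0.23 did not pass (limma, adjusted p = 0.287), although all 3 null values lay below the 3 heterozygous ones, and of 20 alternatives it passed in 1, array weights (adjusted p from 0.0479 to 0.756 over the alternatives). Crybb3, a structural beta-crystallin, was at 15.23 ± 0.10 in null and 15.16 ± 0.20 in heterozygous lenses, a difference of 0.07 ± 0.20 that did not pass (limma, adjusted p = 0.956) and that was −0.08 after scaling arrays to one median and −0.48 on the series matrix values. This Crybb3 probe was at 80.3% to 99.5% of the brightest signal of each array, where saturation was not tested, so a difference near 0 does not show equal levels. A second, much dimmer Crybb3 probe was at 8.74 ± 0.70 in null and 8.64 ± 0.80 in heterozygous lenses. It differed by 0.10 ± 0.44 (limma, adjusted p = 0.975), too imprecise to show equal levels either. Hspb1 and Crybb3 are known from published work on this mutant, possibly on these samples, so their direction here is not independent evidence.

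In null lenses 6 genes were higher, Gpnmb, Lyz1, Mmp12, Ckmt2, Plk3 and Tinag. Gpnmb, a membrane glycoprotein of macrophages and pigment cells, rose from 5.21 ± 0.53 to 10.77 ± 1.22 on the log2 scale (n = 3 each, limma adjusted p = 0.00970), but was detected on only 2 of 3 heterozygous arrays, so the size of its rise is uncertain. The Gpnmb difference of 5.56 was 6.24 without null array 4. Of its other probes, 1 was detected on 0 of 3 heterozygous arrays and was at least 4.19-fold higher (adjusted p = 0.202, at least 2.63-fold without null array 5), and 1, detected on 1 of 3 heterozygous and 2 of 3 null arrays, differed by 0.15 ± 0.25 (adjusted p = 0.909), so the Gpnmb probes disagreed in size. Lyz1, which encodes lysozyme, rose from 4.72 ± 0.35 to 9.66 ± 1.87 (adjusted p = 0.0455), but was detected on only 1 of 3 heterozygous arrays, so the size of its rise is uncertain. The Lyz1 difference of 4.94 was 5.86 without null array 4 and 3.99 without null array 5. Lyz1 and its paralogue Lyz2 are close in sequence, so their probes were not taken as separate evidence. Mmp12, the macrophage elastase, was detected on 0 of 3 heterozygous and 3 of 3 null arrays and was at least 5.73-fold higher in null lenses (adjusted p = 0.0264), a bound set against the lowest signal among the probes detected on each heterozygous array. Ckmt2, the mitochondrial creatine kinase of striated muscle, rose 7.65-fold (difference 2.94 ± 0.30, adjusted p = 0.00970), and its second probe rose by 2.74 ± 0.27 (adjusted p = 0.00970). Plk3, a stress-responsive polo-like kinase, rose 3.49-fold (difference 1.80 ± 0.27, adjusted p = 0.0455). Tinag, a basement membrane antigen named here after its values were seen, passed on 1 of its 2 probes, which was detected on 0 of 3 heterozygous arrays and was at least 2.20-fold higher (adjusted p = 0.0455), and its brighter probe gave 1.89 ± 0.33 (adjusted p = 0.0727). The chemokine Ccl27a, next in order of p, was 2.43-fold higher and did not pass (difference 1.28 ± 0.20, adjusted p = 0.0529).

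**Figure D1:**
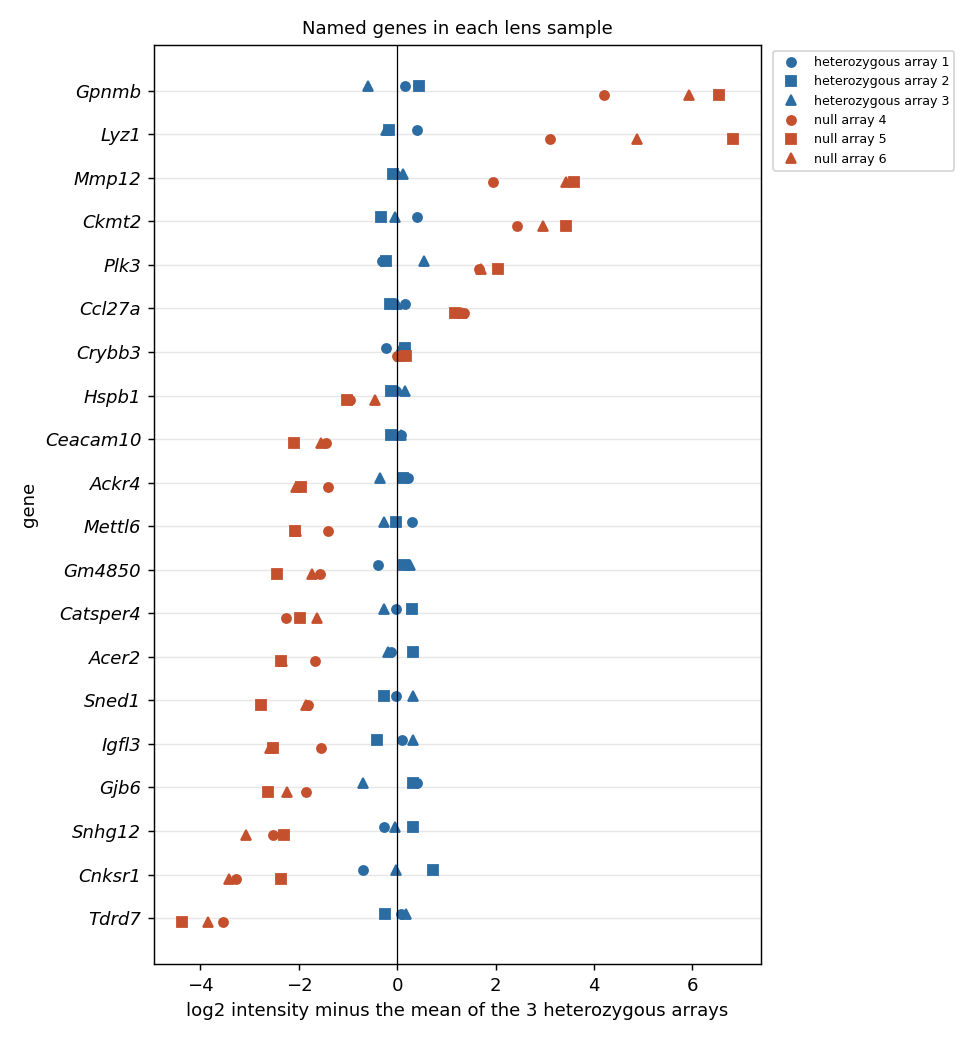
Log2 intensity of 20 named genes in each lens sample (x axis), as the difference from the mean of the 3 heterozygous arrays, with 1 gene per row (y axis), blue symbols for heterozygous arrays 1 to 3 and red symbols for null arrays 4 to 6. The 3 null values lie apart from the 3 heterozygous values for every gene shown except Crybb3, and null array 5 has the highest Gpnmb, Lyz1 and Mmp12.

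Transcripts that were lower in null lenses came from genes of varied function. The largest falls after that of Tdrd7 were in Cnksr1, a scaffold of Ras signalling, which differed by −3.02 ± 0.39 (limma adjusted p = 0.0264, detected on 1 of 3 null arrays), and in Snhg12, a host gene of small nucleolar RNAs, which differed by −2.64 ± 0.26 (adjusted p = 0.00970). Gjb6, a gap junction connexin, fell 4.72-fold from 7.54 ± 0.61 to 5.30 ± 0.39 (adjusted p = 0.0455). Igfl3 fell 4.67-fold (adjusted p = 0.0395), and its second probe gave −2.31 ± 0.37 (adjusted p = 0.0530). Sned1, a protein of the extracellular matrix, fell 4.42-fold (adjusted p = 0.0358), and Acer2, an alkaline ceramidase, fell 4.36-fold (adjusted p = 0.0224). Catsper4, a subunit of the sperm calcium channel, fell 3.87-fold, the predicted gene Gm4850 3.79-fold, the RNA methyltransferase Mettl6 3.60-fold, the atypical chemokine receptor Ackr4 3.50-fold and Ceacam10 3.24-fold, with adjusted p from 0.0264 to 0.0455. Beyond the 12 genes with the largest falls, Serpind1 fell by 1.66 ± 0.25 (adjusted p = 0.0479), and Slc18a2, a vesicular monoamine transporter detected on 0 of 3 null arrays, was at least 2.46-fold lower (adjusted p = 0.0264).

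In all, 27 of 14902 probes passed an adjusted p of 0.05 in limma, 7 higher and 20 lower in null lenses, and 1300 had an unadjusted p under 0.05. Another split of the arrays, 1, 3 and 6 against 2, 4 and 5, gave 1508 at that unadjusted p. The 27 probes named 20 genes, 6 higher and 14 lower, and 6 lower probes had no gene name. Null and heterozygous values did not overlap for any of the 27, and for 15.3% of all probes tested, where chance gives 10%. The count changed when single arrays were left out, which also leaves fewer samples to test, and the 2 were not told apart. Without heterozygous array 1 it was 8, without heterozygous array 3 it was 7 and without null array 6 it was 2. The larger number of lower probes did not hold either, since without null array 4 there were 17 higher and 13 lower, of which 15 were among the 27, and without null array 5 there were 9 higher and 4 lower. Tdrd7 passed whichever array was left out, while Gpnmb, Snhg12 and Ckmt2 passed in 5 of 6 cases and missed without null array 6 (adjusted p = 0.0546, 0.0546 and 0.0641). Each of the other 16 genes missed in at least 3 of the 6 cases, and its highest adjusted p came without null array 6, heterozygous array 1 or heterozygous array 3 and ran from 0.109 for Catsper4 to 0.233 for Serpind1. Scaling arrays to one median in place of quantile normalization left 3 probes, 2 higher and 1 lower, and moved the median of all probes to 0.27 from 0.01. Without heterozygous array 2 and null array 5, left out together after the data were seen, 114 probes passed, 54 higher and 60 lower, and all 27 were among them. With the replicate number as a block, on the series matrix values, 37 passed, 11 higher and 26 lower, and Plk3 (adjusted p = 0.0647), Gm4850 (0.0796) and Tinag (0.0891) no longer did. On those values Lyz1 and Gjb6 missed with the block (0.101 and 0.0577) and without it (0.0716 and 0.0505), and Ccl27a passed with it (0.0445) and without it (0.0398). Over all alternatives the adjusted p of the 19 genes besides Tdrd7 ran from 0.000252 to 0.620.

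Markers of leucocytes and macrophages were higher in null lenses as a group. All 10 measured members of the 24 listed were higher, with a median log2 difference of 2.26 and a mean of 2.08 ± 0.79 (SE), and camera gave the list an adjusted p of 3.13e-09. The call was lost with an estimated correlation between genes (adjusted p = 0.795) and with fry (adjusted p = 0.447), and over all alternatives the adjusted p ran from 4.17e-15 to 0.795. Laptm5, a lysosomal protein of blood cells detected on 2 of 3 heterozygous arrays, differed by 3.74 ± 0.63, Lyz2, the lysozyme of myeloid cells, was at least 10.1-fold higher on its brighter probe and at least 5.50-fold on the other, C1qb, a chain of complement C1q made by macrophages, was at least 5.60-fold higher, and Cd53, a tetraspanin of leucocytes detected on 1 of 3 heterozygous arrays, differed by 1.17 ± 0.29, so the sizes for Laptm5 and Cd53 are uncertain. Of the 10 members, 0 passed over all probes tested in limma and 9 passed when adjusted over the list alone, with 9 at an unadjusted p under 0.05. Of the 10 members, 6 were detected on no heterozygous array, and with these at their bounds the median was 1.92. The filter keeps a marker detected on the 3 null arrays alone, so the count of higher members and their sizes partly follow from it. With no filter on dim probes the median was 0.73 (camera, adjusted p = 4.51e-08). The mean of the list lay 0.90, 3.58 and 1.75 above the heterozygous mean on null arrays 4, 5 and 6, against 0.02, 0.02 and −0.04 on heterozygous arrays 1, 2 and 3. Without null array 5 the median was 1.30 (adjusted p = 1.03e-10), Laptm5 differed by 2.97, and the bounds were at least 4.15-fold and 3.25-fold for the Lyz2 probes and at least 2.61-fold for C1qb. Without null array 4 these values rose, to a median of 3.00 and a Laptm5 difference of 4.53. The bounds were then at least 18.8-fold and 8.74-fold for the Lyz2 probes and at least 9.90-fold for C1qb.

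**Figure D2:**
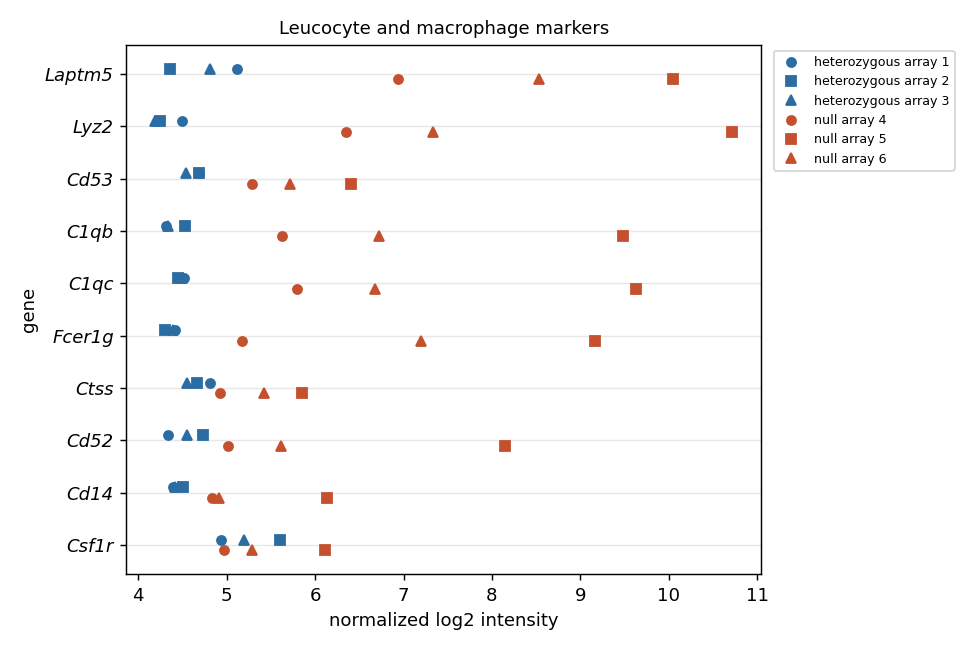
Normalized log2 intensity (x axis) of the 10 measured leucocyte and macrophage markers (y axis) on each array, in blue for heterozygous arrays 1 to 3 and in red for null arrays 4 to 6. Null array 5 is the highest of the 6 arrays for all 10 genes, and the 3 null arrays lie above the 3 heterozygous arrays for 9 of them, Csf1r being the exception.

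Genes of glycolysis and the response to low oxygen were also higher as a group. Of 25 measured members of the 29 listed, 23 were higher, with a median of 0.52 and a mean of 0.54 ± 0.29 (camera, adjusted p = 1.64e-05). The call was lost with an estimated correlation (adjusted p = 0.795, the highest over the alternatives, of which the lowest was 2.24e-07) and with fry (adjusted p = 0.455). Of the 25 members, 0 passed in limma either over all probes or when adjusted over the list alone, with 6 at an unadjusted p under 0.05. Ankrd37, a target of the hypoxia-inducible factor, differed by 1.20 ± 0.32, Egln3, an oxygen-sensing prolyl hydroxylase, by 0.92 ± 0.37, and the glycolytic enzymes Pgam1 by 0.91 ± 0.34 (0.45 ± 0.21 on its second probe) and Pgk1 by 0.86 ± 0.31. The mean of the list was 0.32, −0.45 and 0.13 relative to the heterozygous mean on heterozygous arrays 1, 2 and 3, and 0.25, 0.86 and 0.53 on null arrays 4, 5 and 6. Leucocyte markers moved with it on the null arrays, with means of 0.90, 3.58 and 1.75 on null arrays 4, 5 and 6. Lens epithelium markers moved with it on heterozygous array 2, where their mean was −1.05, against 0.67 and 0.38 on heterozygous arrays 1 and 3. Slc2a1, which is in both lists, was −2.72 there relative to heterozygous arrays 1 and 3. The median was 0.28 without heterozygous array 2, 0.29 without null array 5 and 0.10 without both, where the call ended (adjusted p = 0.191). Without both arrays, 3 lists passed in camera at the preset correlation, leucocyte markers, retinal photoreceptor markers (median 0.75) and cholesterol synthesis (median 0.39). An estimated correlation was not run there, and with all 6 arrays it gave each of these lists an adjusted p of 0.795.

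**Figure D3:**
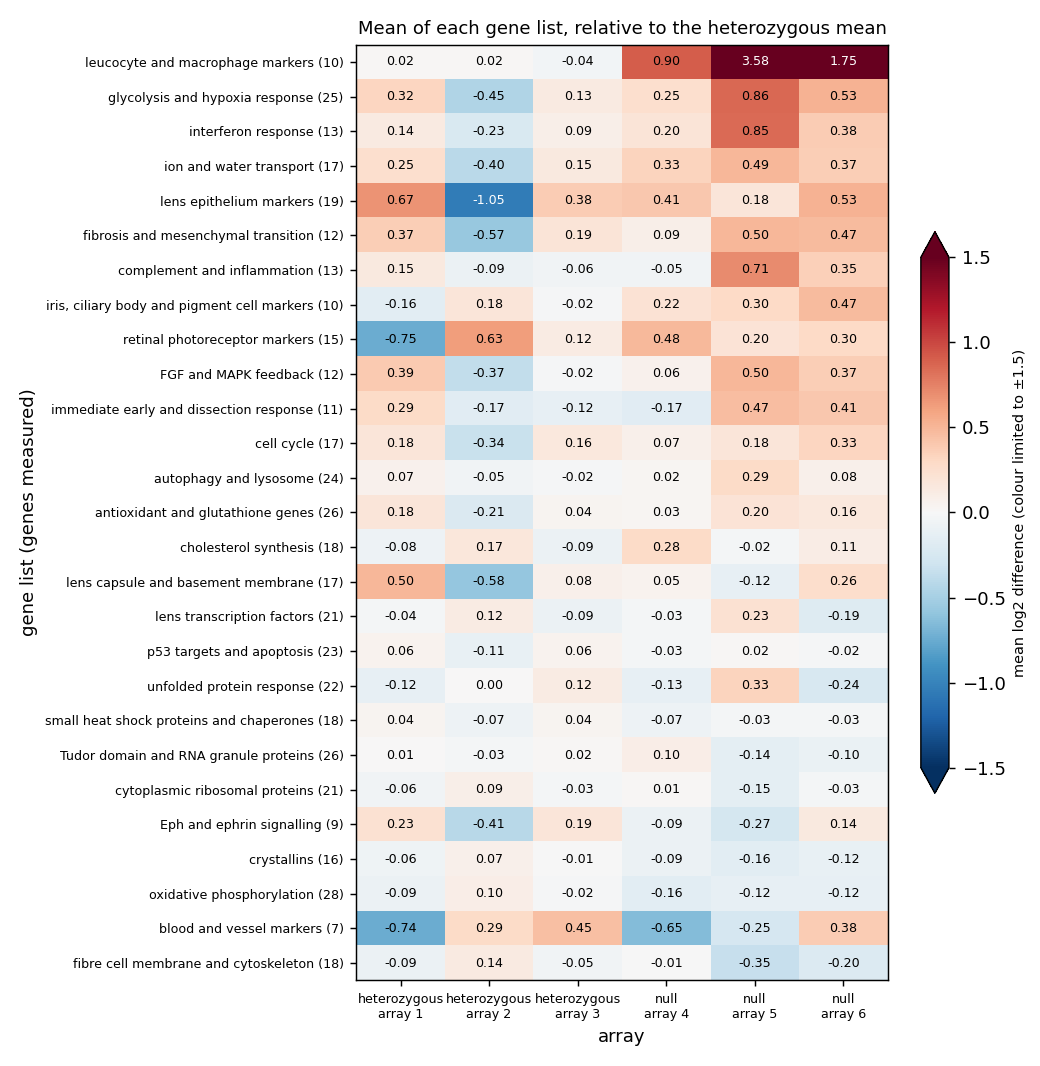
Mean log2 difference of each gene list from the mean of the 3 heterozygous arrays (colour, limited to 1.5 in either direction, with the value printed), for 27 lists (y axis, with the number of genes measured) on heterozygous arrays 1 to 3 and null arrays 4 to 6 (x axis). Leucocyte and macrophage markers reach 3.58 on null array 5, and lens epithelium markers are at −1.05 on heterozygous array 2.

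Crystallins and fibre cell genes, which are the main products of the lens, did not pass as groups, but 11 of 16 crystallins and 3 of 18 fibre cell genes (Mip, Lim2 and Grifin) lay within 2-fold of the brightest signal on all 6 arrays. Saturation was not tested there, so small differences of these genes do not show equal levels. Of 16 crystallins measured, 10 were lower and 6 higher, with a median of −0.06 (camera, adjusted p = 0.257) that was −0.19 after median scaling and −0.59 on the series matrix values, and the list passed in both of these. Crygn differed by −0.47 ± 0.20, and by −0.68 ± 0.20 and −0.69 ± 0.19 on its other probes, and the gamma-crystallins Cryga, Crygf and Crygb by −0.47 ± 0.25, −0.55 ± 0.32 and −0.25 ± 0.19. Of 18 genes of the fibre cell membrane and cytoskeleton, 12 were lower, with a median of −0.14 (adjusted p = 0.111), and this list too passed after median scaling (−0.07) and on the series matrix values (−0.48). Those calls were not particular to lens genes, since ribosomal proteins also passed as lower in camera in both settings (−0.12, adjusted p = 0.00140, and −0.53, adjusted p = 0.000344, of a range up to 0.925). On the series matrix values, the slopes of the rescaling lower bright probes in null lenses whatever their gene. Clic5, a chloride channel protein tied to the cytoskeleton, differed by −1.14 ± 0.30, Caprin2, an RNA-binding protein of fibre cells, by −0.88 ± 0.31 and Birc7, a member of the inhibitor-of-apoptosis family, by −0.49 ± 0.21. Among Tudor domain and RNA granule proteins, the class to which Tdrd7 belongs, 12 of 26 were higher and 14 lower (median −0.04, adjusted p = 0.682, 0.31 after median scaling). The piRNA pathway protein Tdrkh differed by −0.74 ± 0.26. Small heat shock proteins and chaperones gave 11 higher and 7 lower of 18 (adjusted p = 0.772), with a median of 0.09 against a mean of −0.05 and a lower direction in camera. In that list the mitochondrial chaperonin Hspe1 differed by −0.69 ± 0.25 and the co-chaperone Bag3 by −0.62 ± 0.27. Of these 4 lists, each had 0 members past the threshold when adjusted over the list alone, and from 1 to 3 members at an unadjusted p under 0.05 in limma.

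Of 29 lists fixed beforehand, 27 had at least 5 measured genes, and 2 passed in camera. Of the 10 splits of the 6 arrays into 3 and 3, 9 gave at least as many, the real one included. The number of lists was 8 without heterozygous array 1, 5 without null array 4 and 4 without null array 6. With an estimated correlation 0 passed, with 1 list (ion and water transport) at an unadjusted p under 0.05, and with fry, which tests whether the genes of a list move one way on balance, 0 passed and 0 were at an unadjusted p under 0.05. Ion and water transport had 13 of 17 members higher (median 0.41, adjusted p = 0.0517), with the taurine transporter Slc6a6 at 0.96 ± 0.28 and the water channel Aqp1 at 1.96 ± 0.93, which was 0.60 without heterozygous array 2. Complement and inflammation had 10 of 13 higher (median 0.32, adjusted p = 0.0517), and the chemokine Ccl4, detected on 0 of 3 heterozygous arrays, was at least 2.31-fold higher and alone passed when adjusted over the list alone. Interferon response genes had 10 of 13 higher (median 0.31, adjusted p = 0.0517), with B2m at 1.85 ± 0.68 and H2-D1, detected on 2 of 3 heterozygous arrays, at 6.86 ± 1.63 in null and 5.36 ± 0.42 in heterozygous lenses (adjusted p = 0.570), parts of the class I antigen-presenting complex, and without null array 5 these differed by 0.91 and 0.60. Over the alternatives the transport list passed in 5 of 23, the inflammation list in 6 of 23 and the interferon list in 8 of 22. Oxidative phosphorylation had 20 of 28 lower (median −0.13, adjusted p = 0.0568). It passed as lower in 10 of 23 alternatives, with adjusted p from 0.000128 to 0.795, among them median scaling (median 0.04, adjusted p = 0.0338), cyclic loess (0.0472) and the series matrix values (0.000128). Its members included the complex I subunits Ndufb2 at −0.66 ± 0.22 and Ndufb5 at −0.53 ± 0.20. On null arrays 4, 5 and 6 the means were −0.05, 0.71 and 0.35 for inflammation and 0.20, 0.85 and 0.38 for interferon genes. Leucocyte markers had the same order over the null arrays. The inflammation mean on null array 4 lay below the 0.15 of heterozygous array 1, however, where leucocyte markers were near 0. The transport mean was −0.40 on heterozygous array 2, where lens epithelium markers were also low. Both of those lists hold Aqp1, so their shared fall is partly 1 gene counted in both.

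Tdrd7 lies on chromosome 4 in the GRCm38.p6 annotation, and the mice carry genomes of 2 strains, so genes close to it were tested as a set. Of the 100 nearest measured genes, 50 on each side of Tdrd7, 0 passed, against 18 of 8829 elsewhere (Fisher's exact test, two-sided, p = 1), and 3 had an unadjusted limma p under 0.01. So few genes passed that this window could not have shown a lower share. Over the whole of chromosome 4, Cnksr1, Snhg12, Acer2, Catsper4 and Plk3 changed besides Tdrd7. Leaving out Tdrd7 and the leucocyte markers, that is 5 of 574 genes there against 13 of 8345 on other chromosomes (Fisher's exact test, two-sided, p = 0.00460), a comparison chosen after the genes were seen.

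**Figure D4:**
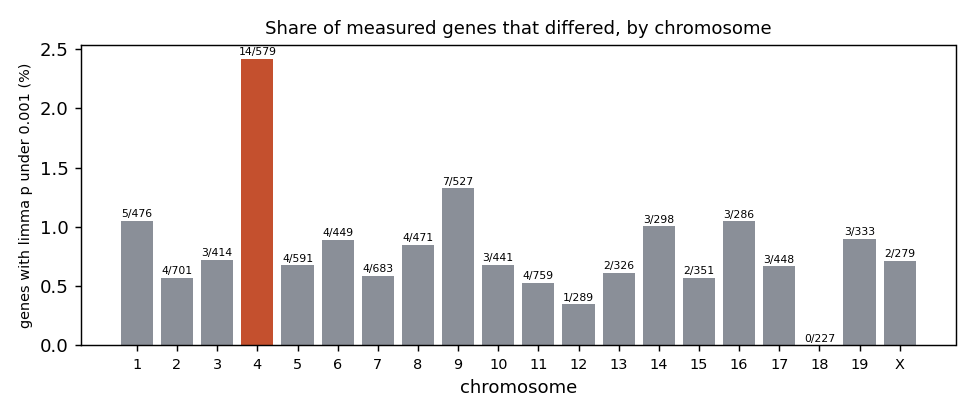
Percent of measured genes with an unadjusted limma p under 0.001 (y axis) on each chromosome (x axis), with the number of genes printed above each bar and chromosome 4, which holds Tdrd7, in red. Chromosome 4 has 14 of 579 genes, 2.42%, and chromosome 9, the next, has 7 of 527, 1.33%. Tdrd7 and the leucocyte markers are counted in the bars, and without them chromosome 4 has 12 of 574 genes, 2.09%.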

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

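The fits without heterozygous array 2 and null array 5 and without the block on the series matrix values were chosen after the data were seen, and all others before. Tdrd7 was lower in null lenses in all 20 other settings and passed in 18, with adjusted p up to 0.120. It missed on the series matrix values as given (−4.08, adjusted p = 0.0640) and with no filter on dim probes (−3.92, adjusted p = 0.120). With no filter its SE was 0.24 against 0.26, but the prior degrees of freedom in limma were 1.73 against 5.32 and its unadjusted p was 5.01e-06 against 7.95e-08. Leaving out each array in turn gave −4.11 to −3.69 for Tdrd7, 2 to 30 probes changed, 0 to 17 higher, 2 to 14 lower and 2 to 8 lists. The number of probes changed (higher and lower in null) was 1 (0 and 1) with no background correction, 9 (4 and 5) with normexp on the signals alone, 11 (6 lower) with neqc at an offset of 50, and 3 (2 and 1) with 7 lists after median scaling. Of the higher probes, cyclic loess gave 12, a detection p under 0.01 gave 4, and trended and robust variances gave 11 with 6 lists. On the series matrix values as given it was 0 (0 and 0) with 1058 probes at an unadjusted limma p under 0.05 and 9 lists, and with no filter 0 (0 and 0) with 2772 and 6 lists. Array weights, which give heterozygous array 2 a weight of 0.264, gave 266 (120 and 146) and 4 lists. Without heterozygous array 2 and null array 5 it was 114 (54 and 60). At an adjusted p of 0.1 it was 80 (31 and 49) and at 0.01 it was 5 (3 and 2), by construction of the threshold. Of the remaining changes the cause was not tested. Detection on all 6 arrays gave 1 list, because most leucocyte markers then drop out, means of all probes gave 5 lists, and camera with an estimated correlation and fry gave 0. The replicate block gave 11 higher probes against 9 without the block on the same values, and it changed no call of a named gene or list besides those given in the report. The slide as a block was not run. Around Tdrd7 the count of changed genes stayed between 0 and 4 and no setting passed (Fisher's exact test).

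Directions turned only where neither value passed. Crybb3 was −0.076 after median scaling, −0.48 on the series matrix values and −0.040 to 0.15 over the arrays left out. Among lists, given as medians while camera decides the direction, immediate early genes turned with no background correction (0.14), normexp alone (0.15), an offset of 50 (0.18), array weights (0.18), the block (0.22) and without heterozygous array 2 and null array 5 (−0.067). Lens capsule genes turned after median scaling (0.33), on the series matrix values (−0.016), with array weights (−0.033) and without those 2 arrays (−0.18). Lens transcription factors turned on the series matrix values (−0.031), with no filter (−0.0073) and with array weights (−0.032), and antioxidant genes after median scaling (0.30) and on the series matrix values (0.015). With no filter, heat shock proteins (0.068) and the unfolded protein response (0.032) turned. Cell cycle genes turned with detection on all arrays (−0.046), and pigment cell markers with a detection p under 0.01 (−0.42) and with fry (−0.30). Without those 2 arrays, Cp and the epithelium list (−0.078 each), FGF feedback (−0.068), blood and vessel markers (−0.055) and ribosomal proteins (−0.0047) turned. Leaving out single arrays, the ranges were −0.18 to 0.32 for immediate early genes, −0.23 to 0.40 for the capsule, −0.15 to 0.62 for the epithelium, −0.12 to 0.16 for transcription factors, 0.023 to 0.69 for photoreceptor markers, −0.066 to 0.0084 for RNA granule proteins and −0.10 to 0.091 for the unfolded protein response. Of all comparisons of 63 named genes with other settings, array by array ones aside, 718 kept their direction and side of the threshold, 120 lost the call, 22 gained it and 3 turned, and of those of 27 lists 394 kept, 5 lost, 32 gained and 24 turned. Dim and very bright probes limit these results, since saturation was not tested and signals near background have no level on the arrays where they were not detected.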

Other observations

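The tests of a lower share of lens RNA, of alleles linked to Tdrd7, of the epithelium markers on heterozygous array 2 and of the count of probes over other splits were chosen after the result was seen. The others were chosen before their own result. The patterns of Gpnmb, Lyz1 and Mmp12, of chromosome 4 and of heterozygous array 2 were themselves first seen in these data. Stress, death and metabolic genes outside the groups above differed in both directions, and none of these lists passed in camera. Of 23 p53 targets and apoptosis genes 12 were higher and 11 lower (median 0.12, mean −0.01, adjusted p = 0.833, a lower direction in camera). The death receptor Fas differed by −1.12 ± 0.29 in null lenses (limma, adjusted p = 0.243), and its other probes gave −1.42 ± 0.27 and −1.09 ± 0.29, while the initiator caspase Casp9 differed by 0.95 ± 0.29 and Cdkn1a, an inhibitor of the cell cycle detected on 0 of 3 heterozygous arrays, was at least 1.90-fold higher (at least 1.22-fold without null array 5). Autophagy and lysosome genes had 19 of 24 higher (median 0.15, adjusted p = 0.312), among them the lysosomal protease Ctsb at 1.14 ± 0.39. The cholesterol transporter Npc1 differed by −1.25 ± 0.30 and alone passed when adjusted over the list alone, but its other probes gave 0.65 ± 0.28 (detected on 2 of 3 heterozygous arrays) and 0.32 ± 0.32. The unfolded protein response had 11 higher and 11 lower (median 0.00, mean −0.01, adjusted p = 0.682), with the phosphatase subunit Ppp1r15a at −0.87 ± 0.36. Antioxidant genes had 17 of 26 higher (median 0.08, adjusted p = 0.519), with the glutathione transferase Gstp1 at 0.78 ± 0.25 (0.78 ± 0.23 and 0.45 ± 0.33 on its other probes). Cholesterol synthesis had 14 of 18 higher (median 0.20, adjusted p = 0.250), and its median was 0.39 (adjusted p = 0.00424) without heterozygous array 2 and null array 5, with adjusted p up to 0.795 over all alternatives.

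Among structural and neighbouring tissues, fibrosis genes had 8 of 12 higher (median 0.40, adjusted p = 0.161), with smooth muscle actin, Acta2, at 0.60 ± 0.22. Retinal photoreceptor markers had 12 of 15 higher (median 0.45, adjusted p = 0.111, 0.86 after median scaling, where they passed, and 0.02 without heterozygous array 1), with Sag, rod arrestin, at 0.96 ± 0.44 and the disc protein Rom1, detected on 2 of 3 heterozygous arrays, at 0.64 ± 0.25, and their array means ran from −0.75 on heterozygous array 1 to 0.63 on heterozygous array 2. Blood and vessel markers had 5 of 7 lower (median −0.30, adjusted p = 0.591, 0.16 after median scaling). Lens epithelium markers had 14 of 19 higher (median 0.20, adjusted p = 0.257, but −0.15 without heterozygous array 2), cell cycle genes 12 of 17 (0.29, 0.250), lens capsule genes 10 of 17 (0.12, 0.855, −0.02 on the series matrix values and −0.23 without heterozygous array 2), FGF and MAPK feedback genes 7 of 12 (0.15, 0.560) and immediate early genes 6 of 11 (0.29, 0.951, −0.18 without null array 5). Lower as a median were lens transcription factors (−0.02, mean 0.00, adjusted p = 0.934, 0.19 after median scaling and 0.16 without heterozygous array 2), Eph and ephrin genes (−0.14, 0.560, 0.23 after median scaling), ribosomal proteins (−0.03, 0.488, past the threshold after median scaling and on the series matrix values) and iris, ciliary body and pigment cell markers (−0.30, mean 0.33, 0.682), in which Gpnmb alone passed and the pigment enzyme Tyrp1, detected on 2 of 3 null arrays, was at −0.69 ± 0.30.

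Gpnmb, Lyz1 and Mmp12 were higher in null lenses. Pigmented tissue left on the lens is argued against, since the 9 other detected iris, ciliary body and pigment cell markers averaged −0.25 ± 0.13 (SE). Of the 10 measured members of that list, Gpnmb included, 3 were detected on all 3 heterozygous arrays, so sizes near background are uncertain. A lower share of lens RNA as the whole cause is argued against too. The 39 markers of the other cell types, these 9 included, averaged 0.00 ± 0.23 (0.00463 before rounding). That average pools tissues on both sides of 0, with photoreceptor markers at 0.33 ± 0.41 and blood and vessel markers at −0.17 ± 0.48. Leucocytes or macrophages in the null samples remain a candidate explanation, as their 10 detected markers averaged 2.08 ± 0.79. Of these markers, 1 was detected on all 3 heterozygous arrays and 1 is in another list. The filter keeps a marker detected on the 3 null arrays alone, so this average partly follows from it. The average includes Lyz2, which is not separate evidence from Lyz1, and it was not computed without Lyz2. Laptm5 was at 8.51 ± 1.56 and Lyz2 at 8.14 ± 2.29 (SD, n = 3) in null lenses. Whether such cells lay in the lens itself or came along at dissection was not tested, and an effect of the null genotype stays open.

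Genes with a limma p under 0.001 were more frequent on chromosome 4 than elsewhere, with 12 of 574 against 61 of 8345, an odds ratio of 2.90 (95% confidence interval 1.41 to 5.48, Fisher's exact test, two-sided, p = 0.00222), without Tdrd7 and the leucocyte markers. Alleles of the 2 strains linked to the Tdrd7 locus may account for this, and an effect of the null genotype itself stays open. Genes that such alleles change together would not be independent, as Fisher's exact test takes them to be, so its interval may be too narrow. The excess did not rest on the nearest genes, since without the 100 neighbours of Tdrd7 the odds ratio was 2.93 (Fisher's exact test, p = 0.00441). How far from Tdrd7 the other genes lie was not analysed. Sequence variants under single probes stay open, because only 3 of the 12 genes had a second probe, and all 3 differed the same way, Ttc39a by −1.38, Ccl27a by 0.78 and Anks6 by −0.18. Without heterozygous array 2 and null array 5 the odds ratio was 2.04 (1.07 to 3.61, Fisher's exact test, p = 0.0195). Of the 10 splits of the 6 arrays into 3 and 3, 2 gave an odds ratio as large as the real 2.90, the highest other being 4.85, and 10 splits are too few for a share under 0.05.

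Lens epithelium markers were low on heterozygous array 2, with a median of −0.81 relative to heterozygous arrays 1 and 3 and 15 of 19 lower, among them Gja1 (−4.83), Aqp1 (−4.09) and Pdpn (−4.07), and Pdgfra, which was not detected on that array. Lower brightness of that array alone is argued against, since 95% of 10000 random lists matched on brightness lay between −0.34 and 0.25 and 0 reached the observed value. A smaller share of epithelial RNA in that sample is a candidate explanation, with fibre cell genes at 0.22 and crystallins at 0.06 on the same scale. No biological explanation was tested, since the labels give this sample nothing that sets it apart from the other heterozygous samples.

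Over the 10 splits of the 6 arrays, 1, the real one, gave as many as 27 probes, and the highest other gave 0, but 10 splits are too few for a share under 0.05. Among the splits of the series matrix values that part all 3 numbered pairs, the real one gave 27 and the other 3 gave 0 each. At an unadjusted limma p under 0.05 in the main values, arrays 1, 3 and 6 against 2, 4 and 5 gave 1508 probes. The real split gave 1300, so by that measure it does not stand out. For the lists, 9 of 10 splits gave at least as many as the real 2. The highest other gave 15, with arrays 1, 5 and 6 against 2, 3 and 4. The number of lists past the threshold in camera at the preset correlation therefore does not set the real split apart. The estimated correlation was 0.93 for the leucocyte list and 0.35 for the glycolysis list, both above the preset one. With estimated correlations neither list passed (camera, adjusted p = 0.795 for each). Whether such correlation or a structure of the samples underlies the counts over the splits was not tested.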
